A study of Homo sapiens with 12 samples.

How the data were processed

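RNA sequencing libraries from 2 human prostate cancer cell lines were compared after treatment with palbociclib or its solvent, dimethyl sulfoxide (DMSO). Per the labels, cells were grown in RPMI-1640 with 10% fetal bovine serum, and each library was built from 1.3 µg of total RNA with a directional Illumina kit. The dose and duration of palbociclib are not given in the sources used here. The labels assign 12 libraries to 4 groups, with 3 libraries each of C4-2 with palbociclib, C4-2 with DMSO, DU145 with palbociclib and DU145 with DMSO. They do not say whether libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

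The authors deposited one table of raw read counts per gene for each line. Per the file headers, the counts labelled C4-2 were made with featureCounts 2.0.1 on paired reads over exons of the Ensembl 107 annotation, with no strand setting, from alignments whose names point to HISAT. Because the kit marks strand and the counting did not use it, reads of a gene and of an overlapping antisense gene cannot be told apart in that table. For the deposited DU145 counts the aligner, counter and strand setting are not given in the sources used here. The submitters' processing notes name the hg38 build, and coordinates are those of the DU145 table. No row of either table lacked a gene identifier. All 37 mitochondrially encoded genes were listed at 0 in the C4-2 table, whereas all 37 had counts in the DU145 table.

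Every value of the column for C4-2 DMSO replicate 3 was 0. That library was left out, so 11 libraries were used and the C4-2 comparison set 3 palbociclib libraries against 2 DMSO libraries in place of the 3 against 3 that had been planned. Total counts were 2608851 to 3489659 per library labelled C4-2 and 16108999 to 16674393 per library labelled DU145, on average 5.33 times as many. A count of 0 in a single library therefore allows up to 0.86 to 1.15 CPM (counts scaled by the library total) in the first table and 0.18 to 0.186 CPM in the second, taking 3 counts as the limit. These limits cover counting error only, since reads without molecular identifiers are not independent molecules. Gene symbols were joined by Ensembl identifier from a reference table, which matched 61757 of 61860 identifiers in the C4-2 table and 56668 of 57167 in the DU145 table, and 56747 identifiers were in both.

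Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered by group with filterByExpr, libraries were scaled by TMM, and the quasi-likelihood F test was used with Benjamini-Hochberg adjustment at 0.05. Each line was fitted alone. A joint fit of the genes in both tables, with line, treatment and their interaction, tested whether the response differed between lines. The interaction is the DU145 log2 fold change minus the C4-2 one. Standard errors (SE) of log2 fold changes were derived from the fitted coefficient and its F statistic, and none was computed where a group was at or near 0 counts. CPM values used library totals and are given as mean ± SD.

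Before the data were examined, 26 gene lists with 822 distinct genes were fixed. They covered DNA replication and E2F targets, G2/M, histones, cyclins with CDKs and pocket proteins, cGAS-STING components, interferon-stimulated genes, cytokines, MHC class I presentation, DNA methylation and heterochromatin, p53 targets, luminal prostate genes, basal and mesenchymal genes, epithelial-mesenchymal transition, neuroendocrine genes, lysosome and autophagy, cholesterol synthesis, fatty acid synthesis, the integrated stress response, ribosome biogenesis, ribosomal proteins, the nuclear-encoded respiratory chain, mitochondrial transcripts, glycolysis and hypoxia, immediate early genes, NRF2 targets, and leukocyte and stromal markers. Lists with at least 5 tested genes were tested against all other genes with camera in limma 3.58.1, at a preset inter-gene correlation of 0.01. The tests, the alternatives and the rule for named genes were fixed at the same time. The rule named 12 genes of the drug target and pathway whatever their result, the 8 largest rises and 8 largest falls per line among called genes with mean CPM of at least 5 and no overlap between groups, up to 4 called members per list with the smallest adjusted p (2 where none was called), and the 6 largest interactions in each direction. Other list members could be given. XIST and Y-linked genes were left out. Some genes that the rule gave are not reported here.

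Replicates were compared by a chi-square over genes with at least 20 counts in a pair of libraries, divided by its degrees of freedom, where 1 is counting noise alone. The ratio was 1.14 to 1.18 within groups labelled C4-2. In DU145 it was 2.36 and 2.37 between replicates 1 and 2 of each group, and 5.41 to 8.34 in pairs that held replicate 3. Between treatments it was 14.94 to 17.34 in the first table and 61.49 to 67.43 in the second. The lowest chi-square p of a difference within a C4-2 group was 1.1e-40 and the highest 1.1e-23, so no pair differed by counting noise alone. Ratios this near 1 do not exclude repeated preparation or sequencing of the same material.

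Replicate numbers come from the sample titles. As a check of pairing, deviations of log2 CPM from the group mean were correlated across genes between treated and control libraries. Same-numbered DU145 libraries correlated at 0.15, 0.24 and 0.47, all above the limit of 0.1, and were treated as pairs in a blocked alternative. Differently numbered ones ranged from -0.38 to 0.27. Palbociclib replicate 1 correlated more with DMSO replicate 2 (0.27) than with DMSO replicate 1, so the pairing of replicates 1 and 2 is weakly marked. The libraries labelled C4-2 were not taken as pairs by this rule.

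The main fits and the list tests were run on simulated counts drawn from the real means, depths and spread, the fits with 200 changed genes. The replicate block, other scalings, other filters and thinning were not run on them. In the real fits 51.8% of tested genes were called in C4-2 and 58.1% in DU145, a far larger share. Scaling where so many genes change was thus not tested. In the DU145 simulation over 15096 genes, edgeR recovered 70.8% of the 1.5-fold, 89.4% of the 2-fold and 96.9% of the 4-fold changes, with 10 false calls among 178. In the C4-2 simulation over 11726 genes it recovered 74.2%, 95.5% and 100%, with 8 false calls among 184. For the interaction over 17595 genes the shares were 36.4%, 61.2% and 58.5%, with 8 false calls among 111. In each of the 3 simulations camera called a list raised 1.5-fold and 0 other lists. The list was raised in separate draws with few other changed genes. Genes were drawn independently, so false calls that come from correlation between genes could not arise there.

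Alternatives were DESeq2 1.42.0, RLE size factors, library totals without TMM, no filter other than 1 count in total, a filter of 1 CPM in at least 3 libraries, limma-voom, a 2-fold minimum, the replicate block, all libraries in one fit, each library left out, an estimated inter-gene correlation (with which camera also uses the residual degrees of freedom), fry, and lists without shared genes. Alternatives chosen after seeing the data were DU145 counts thinned to the mean C4-2 depth, DU145 without both libraries numbered 3, the interaction over genes tested in both lines, and fits without genes of chromosome 6 from 28 to 34 Mb. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.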

Results

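The series asked how CDK4/6 acts on the cGAS-STING pathway of innate immunity in prostate cancer cells, and which part of that action needs RB1. Palbociclib inhibits CDK4 and CDK6, the kinases that phosphorylate RB1 and thereby release E2F transcription factors. C4-2 is a castration-resistant derivative of LNCaP with intact RB1, and DU145 is a line from a brain metastasis that is known to lack functional RB1. Transcripts were counted in 11 libraries, with 3 palbociclib and 2 DMSO libraries labelled C4-2 and 3 of each labelled DU145. Totals ran from 2608851 to 3489659 counts in the first set and from 16108999 to 16674393 in the second. The libraries labelled C4-2 thus had the lower precision for rare transcripts, and the 2 sets lie in separate tables with different counting.

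The transcripts that mark each line were examined first. Libraries labelled C4-2 held 0 counts of KLK3 (prostate-specific antigen), KLK2, ACP3 and FOLH1 in all 5 libraries, although these are luminal prostate genes. HOXB13 was at 0.669 ± 0.622 CPM (SD, n = 5) and FOXA1 at 2.62 ± 1.05 CPM. The most abundant transcript was FN1, fibronectin, at 19670 ± 1110 CPM. COL6A3 (2574 ± 39.9 CPM), TGFBI (1928 ± 26.2 CPM), SPARC (1759 ± 89.4 CPM) and VIM (1501 ± 245 CPM) were also high. Libraries labelled DU145 held KRT8 at 1524 ± 243 CPM (n = 6), KRT7 at 691 ± 308 CPM and CDKN2A at a mean of 402 CPM, with CDH1 at 1.5 ± 0.601 CPM and EPCAM at 0.887 ± 0.336 CPM. FN1, COL6A3, SPARC, CDH1 and EPCAM were chosen after their values were seen. Because the luminal transcripts do not match the C4-2 label, and CDH1 and EPCAM were low for the epithelial line DU145, groups are called by their labels throughout, and RB1 status is that of the named lines, not a measurement.

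**Figure D1:**
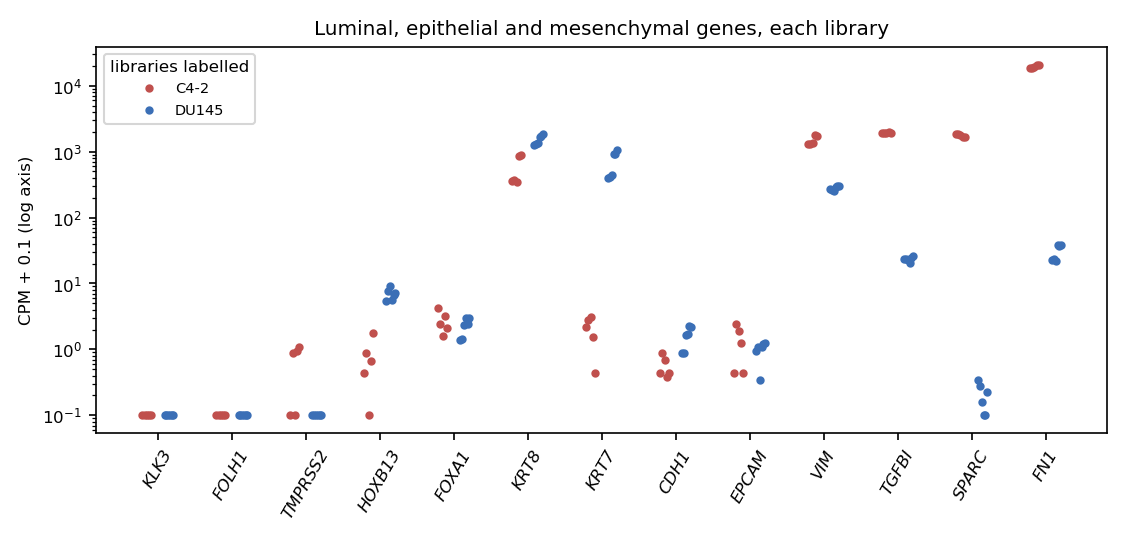
CPM plus 0.1 (log axis) of 13 luminal, epithelial and mesenchymal genes, 1 point per library, for the 5 libraries labelled C4-2 and the 6 labelled DU145. KLK3 and FOLH1 were at 0 in every library of both sets, and FN1 had a mean of 19670 CPM in the libraries labelled C4-2 against 30.1 CPM in those labelled DU145.

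In the libraries labelled C4-2, palbociclib lowered the genes of DNA replication and mitosis and raised interferon-stimulated and amino-acid stress genes. Of 56 tested E2F and S-phase genes, 54 fell and 0 rose, with a median log2 fold change of -1.5. They included RRM2, a ribonucleotide reductase subunit (-2.84, SE 0.07, 43.6 ± 4.09 against 305.0 ± 14.0 CPM), MCM7 of the replicative helicase (-2.11) and PCNA (-1.96). All 57 tested G2/M genes fell, with a median of -1.36, among them the proliferation marker MKI67 (-1.94, SE 0.04), TOP2A (-1.46) and CDC20 (-1.76). Adjusted over the list alone, the counts of both lists were the same, at 54 and 57. Both lists passed camera (adjusted p = 4.68e-42 and 9.09e-86) and held with an estimated correlation (adjusted p = 0.0212 for each). In all, 6184 of 11943 tested genes passed edgeR's threshold, 3011 higher and 3173 lower, and 1161 of these changed at least 2-fold (614 higher and 547 lower). The majority direction depended on scaling, with 3366 higher and 2771 lower with library totals in place of TMM.

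Among cell-cycle regulators, CCND1 (cyclin D1) rose by 1.12 in log2 (SE 0.04, adjusted p = 5.42e-28) in the libraries labelled C4-2. CDK4 (-0.39, SE 0.10, adjusted p = 0.00138) and CDK6 (-0.50, SE 0.05, adjusted p = 6.18e-12) fell. RB1 was at 60.5 ± 6.76 CPM with palbociclib (n = 3) and 62.8 ± 7.34 CPM with DMSO (n = 2), with an edgeR adjusted p of 0.409. CDKN2C (-1.71) and RBL1 (-1.72), a pocket protein related to RB1, fell. Of the 17 tested members of the cyclin and pocket protein list, 3 rose (CCND1, E2F5 and RBL2) and 9 fell, both over all genes and adjusted over the list alone, and the list did not pass camera (adjusted p = 0.223).

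Components of the cGAS-STING pathway went both ways in the libraries labelled C4-2. CGAS, the DNA sensor, fell by 0.58 in log2 (SE 0.15, adjusted p = 0.0015), STING1 fell by 0.64 (SE 0.17, adjusted p = 0.00183) and the transcription factor IRF3 fell by 0.69 (SE 0.12, adjusted p = 3.88e-06). The kinase TBK1 had a change of 0.24 (SE 0.12, adjusted p = 0.0917), which passed with library totals in place of TMM (0.29, adjusted p = 0.0417). SAMHD1 (1.06), TRIM56 (1.0) and IFI16 (0.74) rose. Of 24 tested pathway components, 10 rose and 5 fell, both over all genes and adjusted over the list alone, and camera pointed higher without passing (adjusted p = 0.199). IFNB1 had 0 to 2 counts per library, CXCL10 had 4 to 11, CDKN2A had 0 or 1, and CCL5 had 0 in each, which allows up to 0.86 to 1.15 CPM, and all 4 were too low to be tested in the fit of this line.

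Interferon-stimulated genes rose in 46 of 54 tested cases in the libraries labelled C4-2 (47 adjusted over the list alone), with a median of 0.88, and GBP2 fell. IFI44L (2.22, SE 0.08), OAS2 (1.83), OAS1 (1.49), ISG15 (1.41) and IFIT1 (0.85) were among those that rose. The list passed camera (adjusted p = 8.41e-21) and held with an estimated correlation (adjusted p = 0.0385). Cytokine genes went both ways, with 11 of 27 higher (12 adjusted over the list alone) and 6 lower. IL6 (2.02) and CXCL5 (1.21) rose and CCL2 (-2.35) fell. That list's camera call (adjusted p = 0.0168) was lost with an estimated correlation (adjusted p = 0.118) and without palbociclib replicate 1 (adjusted p = 0.0645). MHC class I genes rose in 10 of 16 cases, including B2M (0.77), and CALR fell (-0.60). That call (adjusted p = 0.00489) was also lost with an estimated correlation (adjusted p = 0.115). TAP1, TAPBP and HLA-E, at 0.52, 0.195 and 1.17 CPM over the C4-2 libraries, were too low to test there, as were many other genes of the MHC region in that table.

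Stress and catabolic genes rose in the libraries labelled C4-2. Of 34 integrated stress response genes, 29 rose and 4 fell, with a median of 1.08. CTH of cysteine synthesis (3.13, SE 0.15), the cystine transporter SLC7A11 (2.57, SE 0.04), asparagine synthetase ASNS (2.58, SE 0.37) and CHAC1 (2.08) were examples. NRF2 targets rose in 15 of 21 cases, among them TXNRD1 (0.77) and FTL (0.64). Lysosome and autophagy genes rose in 33 of 42 cases, including SQSTM1 (1.35), TPP1 (1.18) and MAP1LC3B (1.16). These 3 lists passed camera (adjusted p = 7.54e-39, 9.26e-13 and 1.89e-10) and held with an estimated correlation (adjusted p = 0.0209, 0.023 and 0.0249). Counts adjusted over the list alone were identical for all 3.

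Genes of protein and DNA-methylation machinery fell in the same libraries. Ribosome biogenesis genes fell in 24 of 29 cases (FBL -1.83, NCL -0.92), with 0 higher (1 adjusted over the list alone), and ribosomal protein genes in 43 of 59 (46 adjusted over the list alone; RPL7A -0.49). Both held with an estimated correlation (adjusted p = 0.0485 and 0.0304). Of 19 DNA methylation and heterochromatin genes, 11 fell (12 adjusted over the list alone), including UHRF1 (-2.52), DNMT1 (-1.64) and HELLS (-1.33), and 2 rose. That call (camera adjusted p = 5.64e-05) was lost with an estimated correlation (adjusted p = 0.118). Respiratory chain genes fell in 25 of 44 cases (ATP5F1A -0.59), and basal and mesenchymal genes fell in 12 of 20 (TNC -0.78, CAV1 -0.69) and rose in 4. These 2 calls (adjusted p = 0.0106 and 0.0168) were lost with an estimated correlation (adjusted p = 0.115 and 0.118), and the second also with library totals in place of TMM (adjusted p = 0.0696). Ribosomal protein, ferritin and histone genes have near-identical copies, and their counts are uncertain to that extent.

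The largest rises in the libraries labelled C4-2 by the fixed rule were SLFN5 (3.32, SE 0.09), CTH, NBR2, NHSL1-AS1, H2AC6, PPIL6, ASNS and SLC7A11. NBR2 and NHSL1-AS1 lie beside or antisense to other genes, which counting without strand cannot separate. The largest falls were KIFC1 (-6.01), CLDN2 (-4.19), FAM111B (-3.67), HAS3 (-3.32), E2F8 (-3.25), CCNE2 (-3.03), RRM2 and MCM10 (-2.81). KIFC1 had 33 and 119 counts in the 2 DMSO libraries and 0 to 2 with palbociclib. The C4-2 KIFC1 log2 fold change was -4.70 without DMSO replicate 2, -6.75 without DMSO replicate 1, -6.76 without palbociclib replicate 3 and -6.77 with the replicate block. CLDN2 was at 0.852 ± 0.566 CPM with palbociclib, and the C4-2 CLDN2 log2 fold change was -4.87 without palbociclib replicate 3. KIFC1 lies in the MHC region, where most genes were low in this table.

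Libraries labelled DU145 gave 8924 calls among 15361 tested genes, 4431 higher and 4493 lower, and 2055 of these changed at least 2-fold. The majority direction turned with RLE size factors (4516 higher and 4414 lower) and with DESeq2 (4153 and 3905). Lysosome, cholesterol synthesis and ribosome biogenesis genes rose, and amino-acid stress genes fell. Of 43 lysosome and autophagy genes, 35 rose, with a median of 0.69, including NEU1 (2.13, SE 0.08), GPNMB (2.52), ATP6V1C1 (1.56) and TPP1 (1.43). Cholesterol synthesis genes rose in 22 of 26 cases (median 0.57), among them MVK (1.26) and HMGCS1 (0.97). Ribosome biogenesis genes rose in 23 of 30 cases, including NOP16 (1.26) and WDR43 (1.09), and 0 fell. Integrated stress response genes fell in 24 of 35 cases (25 adjusted over the list alone), with a median of -0.50. DDIT4 (-1.76, SE 0.08), SESN2 (-1.65), SLC7A11 (-1.50), PCK2 (-1.43) and PSAT1 (-1.14) were examples. For the first 3 lists the counts adjusted over the list alone were identical. These 4 lists passed camera (adjusted p = 2.41e-20, 7.24e-09, 3.41e-06 and 4.85e-10) and held with an estimated correlation (adjusted p = 0.031, 0.031, 0.0314 and 0.031).

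Proliferation genes showed no common fall in the libraries labelled DU145. Of 55 E2F and S-phase genes, 26 fell and 10 rose (27 and 11 adjusted over the list alone), with a median of -0.15. EXO1 (-1.85, SE 0.08) and PRIM1 (-1.44) fell, while ORC6 (0.91) and FEN1 (0.79) rose. The camera call of that list (adjusted p = 0.0409) was lost with an estimated correlation (adjusted p = 0.255) and without palbociclib replicate 3 (adjusted p = 0.0568). G2/M genes rose in 31 of 61 cases and fell in 7 (32 and 8 adjusted over the list alone), with a median of 0.18. CKS2 (1.08), TPX2 (0.76) and AURKA (0.70) were among those that rose, and MKI67 rose by 0.36 while TOP2A fell by 0.27. Its camera call (adjusted p = 0.0112) was lost with an estimated correlation (adjusted p = 0.458).

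The drug targets rose in the libraries labelled DU145. CDK6 changed by 0.68 (SE 0.06, adjusted p = 8.52e-08) and CDK4 by 0.52 (SE 0.07, adjusted p = 2.36e-06). CCND1 changed by 0.18 (SE 0.07, adjusted p = 0.0314), a call that was lost with library totals (adjusted p = 0.052) and without palbociclib replicate 1 or 2 or DMSO replicate 1 or 2 (adjusted p = 0.0647, 0.0506, 0.127 and 0.139). RB1 transcript was at 97.4 ± 6.39 CPM with palbociclib and 88.2 ± 8.22 CPM with DMSO (n = 3 each). Its change of 0.17 (edgeR adjusted p = 0.0694) passed with the replicate block (adjusted p = 0.00248) and without palbociclib replicate 3 (adjusted p = 0.0124). CDKN2A changed by 0.13 (adjusted p = 0.204), which passed with the replicate block (adjusted p = 0.0087) and without palbociclib replicate 1 (adjusted p = 0.0295). CDKN1A, the p21 inhibitor of CDKs, rose by 1.47 in log2 (SE 0.06), while CDKN1C (-1.43) and CDKN2C (-1.11) fell. The cyclin and pocket protein list, with 9 of 20 higher (10 adjusted over the list alone) and 8 lower, did not pass camera (adjusted p = 0.742).

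Within the cGAS-STING pathway, CGAS rose by 0.62 in log2 (SE 0.09, adjusted p = 2.07e-05) in the libraries labelled DU145. IRF3 rose by 0.31 (SE 0.09, adjusted p = 0.00843), a call lost without DMSO replicate 1 (adjusted p = 0.0723). TBK1 changed by 0.22 (SE 0.10, adjusted p = 0.0592), which passed with the replicate block (adjusted p = 0.0172), without palbociclib replicate 2 (adjusted p = 0.0269) and without DMSO replicate 2 (adjusted p = 0.0328). STING1 had 2 to 8 counts per library and was not tested. NLRX1 (-1.10) and IKBKE (-1.51) fell. Of 28 tested components, 12 rose and 9 fell (13 and 9 adjusted over the list alone). The list's median was 0.14, its mean -0.11, and camera pointed higher without passing (adjusted p = 0.404). IFNB1 had 0 counts in all 6 libraries, which allows up to 0.18 to 0.186 CPM per library. CCL5 had 2 to 7 counts with palbociclib against 0 or 1 with DMSO, and CXCL10 had 6 to 9 against 1, both too few to be tested.

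**Figure D2:**
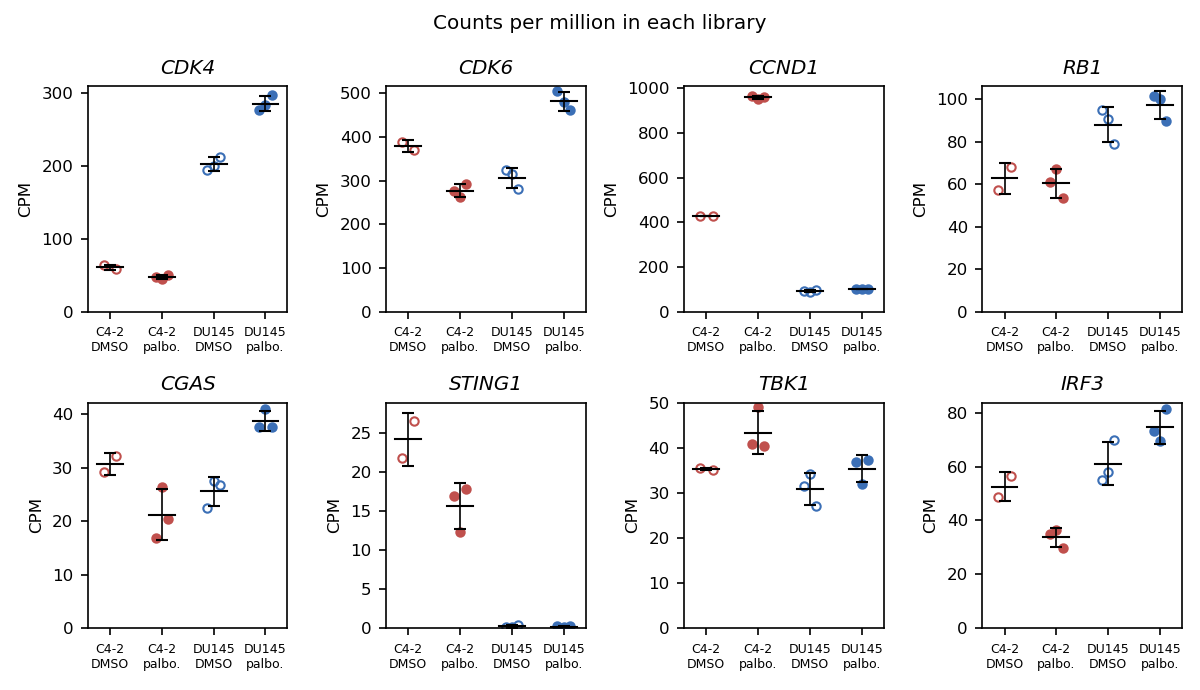
CPM (vertical axis) of 8 genes of the drug target and the pathway in each library, by label and treatment, with open circles for DMSO, filled circles for palbociclib, and bars for the mean and SD of the group. CGAS fell from 30.7 to 21.3 CPM in the libraries labelled C4-2 and rose from 25.6 to 38.8 CPM in those labelled DU145.

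Interferon-stimulated genes were mostly lower in the libraries labelled DU145. Of 41 tested, 22 fell and 7 rose, with a median of -0.35. SAMD9L (-2.58, at 4.81 ± 0.19 CPM with DMSO), PARP9 (-1.23) and IFITM3 (-0.78) fell, while ISG15 (1.18), IFIT1 (1.74) and IFIT2 (0.88) rose. The camera call (adjusted p = 0.0409) was lost with an estimated correlation (adjusted p = 0.198), without palbociclib replicate 1 (adjusted p = 0.0605), without DMSO replicate 3 (adjusted p = 0.0522) and without both libraries numbered 3 (adjusted p = 0.0601). Cytokine genes rose in 11 of 19 cases, including RELB (1.21), ICAM1 (1.19), CSF1 (1.17) and NFKB2 (1.03). p53 targets rose in 16 of 27 cases, with GDF15 (2.34), AEN (1.59) and CDKN1A as examples, and XPC fell (-1.26). Immediate early genes rose in 18 of 23 cases, among them DUSP1 (1.41), JUN (1.38) and FOSL1 (1.37). Fatty acid synthesis genes rose in 12 of 17 cases (ACSL1 1.21, SCD 0.75). These 4 camera calls (adjusted p = 0.002, 0.000396, 1.22e-06 and 0.0024) were lost with an estimated correlation (adjusted p = 0.198, 0.165, 0.198 and 0.176).

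Basal and mesenchymal genes fell in 12 of 20 cases in the libraries labelled DU145 (14 adjusted over the list alone), including ITGB4 (-1.42), KRT7 (-1.20) and AXL (-1.06). Luminal prostate genes fell in 12 of 24 cases. Ribosomal protein genes fell in 36 of 60 cases (RPS12 -0.63) and mitochondrial transcripts in 10 of 13 (12 adjusted over the list alone; MT-CO1 -0.70). The mitochondrial share of counts was 3.07 to 3.37% with palbociclib and 4.40 to 4.92% with DMSO. These 4 camera calls (adjusted p = 1.01e-05, 0.0436, 0.0024 and 0.0024) were lost with an estimated correlation (adjusted p = 0.198, 0.198, 0.407 and 0.434). The luminal prostate list also lost its call without palbociclib replicate 1 or 2 (adjusted p = 0.0605 and 0.0539) and with the stricter filter (adjusted p = 0.0503).

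By the fixed rule, the largest rises in the libraries labelled DU145 were EFCAB12 (4.59, SE 0.19), TNFRSF14 (4.28, SE 0.11), CAVIN4 (4.21), CCDC17 (3.38), IGFL2-AS1 (3.14), CXCR4 (2.98), SLC9A3-AS1 (2.9) and SLC9A3 (2.70). SLC9A3 and its antisense partner cannot be separated, since strand use in the counting is not stated. The largest falls were DLX3 (-4.22), SLC12A3 (-3.83), BOLA2B (-3.67), LBH (-3.62), MAP2K6 (-3.51), LINC01133 (-3.15), SLCO2A1 (-3.10) and DTX4 (-2.95). BOLA2B has a near-identical copy and rested on DMSO replicate 1, with 455 counts there and 12 to 15 in each of the other libraries. Without that replicate its change was -0.20 (adjusted p = 0.718).

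The difference between lines was tested directly by the interaction, which passed for 6064 of 18139 genes, 3337 with the higher change in DU145 and 2727 with the lower. That balance turned with library totals in place of TMM (2759 and 3291) and among changes of at least 2-fold (1129 and 1323). G2/M genes had a median interaction of 1.60 and passed in 58 of 61 cases. E2F and S-phase genes had a median of 1.5 and passed in 48 of 56. Ribosome biogenesis (1.0), cholesterol synthesis (0.79), DNA methylation and heterochromatin (0.69) and fatty acid synthesis genes (0.44) also had the higher change in DU145. Integrated stress response (-1.43), interferon-stimulated (-0.94) and NRF2 genes (-0.60) had the lower. These 9 lists held with an estimated correlation, at adjusted p of 0.000112 to 0.0426. Of the 57 interferon-stimulated genes in the joint fit, 41 could be tested in DU145 alone. The others were too low there for a DU145 change to be measured. Among all interaction calls, 110 had a group at 0 counts. CTH (-4.38), CHAC1 (-4.53), MKI67 (2.33) and CGAS (1.24, SE 0.20, adjusted p = 6.40e-06) were single examples.

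**Figure D3:**
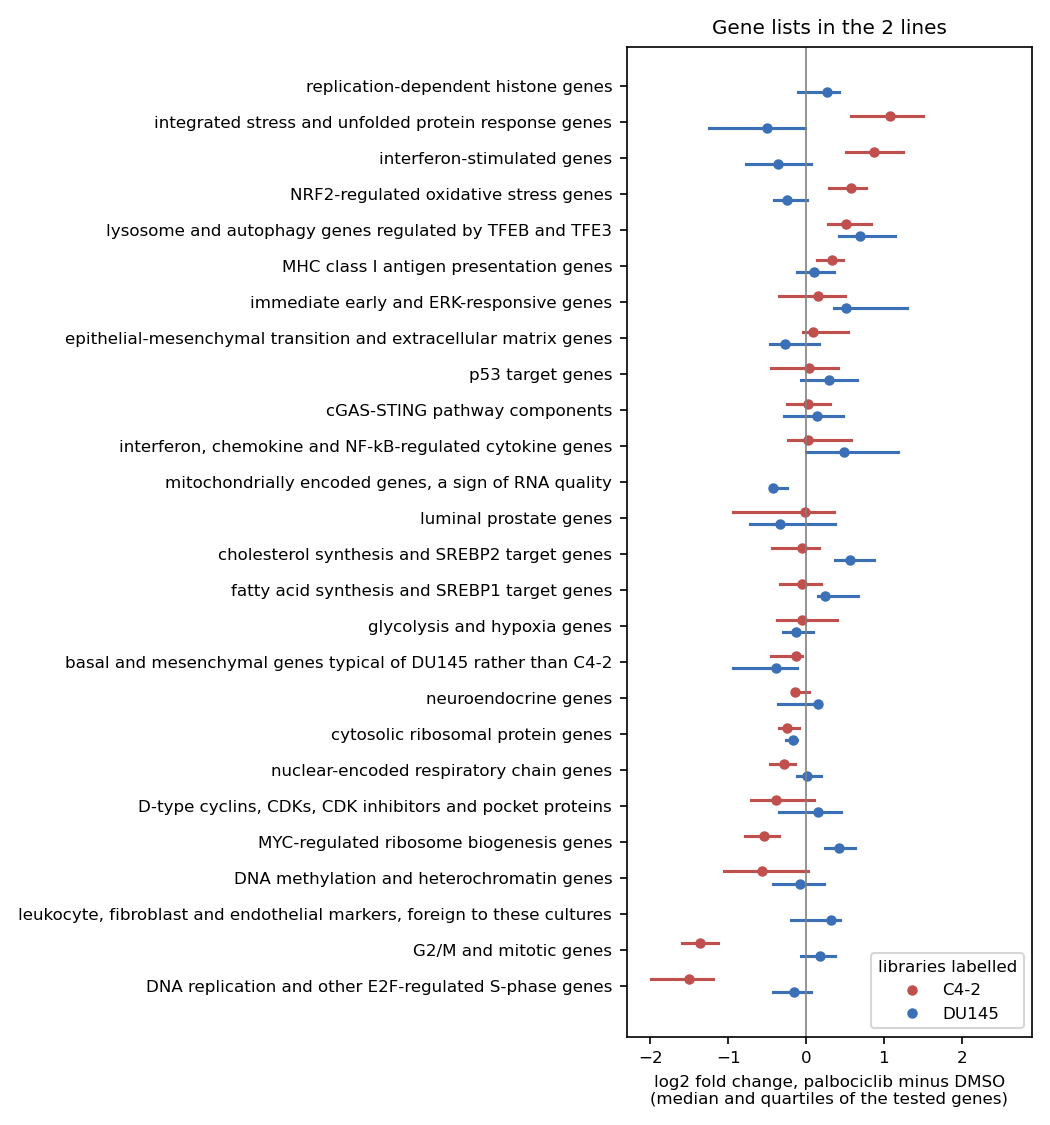
Median (point) and quartiles (bar) of the log2 fold change, palbociclib minus DMSO, over the tested genes of each list with at least 5 of them, for libraries labelled C4-2 and DU145. G2/M genes had medians of -1.36 and 0.18 and integrated stress response genes 1.08 and -0.50, in that order of labels.

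Another 7 lists passed the interaction's camera test only with the preset correlation. Respiratory chain, immediate early, cyclin and pocket protein, cytokine, p53 and lysosome genes had adjusted p of 0.125, 0.22, 0.0635, 0.139, 0.215 and 0.22 with an estimated correlation, and basal and mesenchymal genes 0.218. The cytokine, p53 and lysosome calls (adjusted p = 0.0385, 0.0431 and 0.0431) were also lost when single libraries were left out. Without DU145 palbociclib replicate 3 they were 0.0646, 0.0654 and 0.0646, and without DU145 DMSO replicate 3 they were 0.053, 0.073 and 0.0539. With library totals the p53 and lysosome calls were lost too (adjusted p = 0.0607 and 0.123), and all 3 were lost with DU145 thinned to the C4-2 depth (adjusted p = 0.231, 0.226 and 0.145 in the order cytokine, p53 and lysosome). The p53 call was lost as well without C4-2 palbociclib replicate 1, C4-2 DMSO replicate 2, DU145 palbociclib replicate 2 and DU145 DMSO replicate 2 (0.0544, 0.0523, 0.0579 and 0.0691). The lysosome call was lost without C4-2 palbociclib replicate 2, C4-2 DMSO replicate 1, DU145 palbociclib replicate 1 or 2 and DU145 DMSO replicate 1 or 2 (0.0607, 0.0596, 0.0709, 0.0579, 0.0727 and 0.0938). In all 3 comparisons, counts adjusted over the list alone differed from those over all genes by at most 3 genes in any list.

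Across the 11007 genes tested in both lines, 1930 were called in the same direction, 976 higher and 954 lower, where independent lists would share 1806. Another 1794 were called in opposite directions, against 1808 for independent lists. Log2 fold changes of the 2 lines correlated at 0.05 (Pearson) and 0.03 (Spearman) across genes, which are not independent replicates. SQSTM1 (1.35 and 1.21), TPP1 (1.18 and 1.43), FNIP1 (0.99 and 1.57), ISG15 (1.41 and 1.18) and IL6 (2.02 and 2.39) rose in both, in the order C4-2 and DU145, and CDKN2C (-1.71 and -1.11) and RBL1 (-1.72 and -0.62) fell in both. Genes called in both lines in the same direction numbered 1267 with DESeq2 calls.

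The pathway's named genes lie at these hg38 positions. CDK4 (ENSG00000135446) spans chromosome 12 from 57747727 to 57756013 and CDK6 (ENSG00000105810) chromosome 7 from 92604921 to 92836594. RB1 (ENSG00000139687) spans chromosome 13 from 48303726 to 48599436 and CCND1 (ENSG00000110092) chromosome 11 from 69641087 to 69654474. CGAS (ENSG00000164430) spans chromosome 6 from 73413515 to 73452276, and STING1 (ENSG00000184584), listed under its older symbol TMEM173, chromosome 5 from 139475534 to 139482935. TBK1 (ENSG00000183735) spans chromosome 12 from 64451880 to 64502108 and IRF3 (ENSG00000126456) chromosome 19 from 49659569 to 49665875. All are annotated as protein-coding.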

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

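The tests of depth, scaling and separate tables in this part were chosen after the results were seen. Groups of 3 or fewer libraries were not examined for single outlying samples. Each result here passed the interaction test of a difference in response to palbociclib between the libraries labelled C4-2 and DU145, given as the DU145 minus the C4-2 log2 change. The test passed for 6064 genes. List medians were 1.60 for G2/M, 1.5 for E2F and S-phase, 1.0 for ribosome biogenesis, 0.79 for cholesterol synthesis, 0.72 for immediate early, 0.69 for DNA methylation and heterochromatin, 0.58 for cyclin and pocket protein, 0.45 for cytokine, 0.44 for fatty acid synthesis, 0.40 for p53, 0.36 for respiratory chain and 0.26 for lysosome genes. They were -1.43 for integrated stress response, -0.94 for interferon-stimulated (41 of 57 genes testable in DU145 alone), -0.60 for NRF2 and -0.17 for basal and mesenchymal genes. Of these lists, 7 lost their call with an estimated correlation: respiratory chain (adjusted p = 0.125), immediate early (0.22), cyclin and pocket protein (0.0635), cytokine (0.139), p53 (0.215), lysosome (0.22) and basal and mesenchymal genes (0.218). The cytokine, p53 and lysosome calls were also lost with DU145 thinned to the C4-2 depth (adjusted p = 0.231, 0.226 and 0.145).

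Among the genes named in advance, the interaction was 1.24 for CGAS, 1.21 for CDK6, 1.04 for IRF3, 0.94 for CDK4 and -0.91 for CCND1. It was 2.6 for CXCL10 (adjusted p = 0.0306), which rests on 1 to 11 counts per library. The largest interactions by the fixed rule were 8.28 for CXCR4, 6.54 for KIFC1, 6.22 for GAS1, 5.92 for MIR3667HG, 5.76 for S100A3 and 5.64 for PRDM1, and -7.82 for ZNF521, -6.78 for RING1, -6.32 for PDCD4-AS1, -6.14 for TRIM29 and -5.92 for FAM120B. Of the 12 genes that the rule gave, 11 were under 1 CPM in the libraries labelled C4-2, so their fitted values are no bounds and rest on a few counts there. KIFC1, the exception, had 33 and 119 counts in the DMSO libraries labelled C4-2 and 0 to 2 with palbociclib. KIFC1 and RING1 lie in the MHC region, where most genes were low in the C4-2 table.

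The pattern weighed is that list responses differed between the 2 labels, which an interaction shows whether or not the directions are opposite. E2F and S-phase genes had medians below 0 under both labels (-1.5 in C4-2 and -0.15 in DU145). The 5 lists examined were those with the lowest interaction adjusted p (E2F and S-phase, G2/M, integrated stress response, interferon-stimulated and ribosome biogenesis). With DU145 thinned to the mean C4-2 depth, 5 of 5 kept their interaction call and direction, with medians of 1.44, 1.57, -1.51, -1.13 and 0.96. This argues against depth for these 5 lists, whereas the cytokine, p53 and lysosome calls were lost. With library totals in place of TMM, 5 of 5 also kept call and direction, at 1.39, 1.49, -1.53, -1.04 and 0.89. This argues against scaling for the same 5 lists, whereas the p53 and lysosome calls were lost. Because the 5 lists were picked for their low adjusted p, both tests were likely to be passed. The argument rests on medians that stayed near their main values of 1.5, 1.60, -1.43, -0.94 and 1.0. Separate processing or culture of the 2 sets cannot be told apart from the lines, since 0 tables hold both. A difference in RB1 function between the named lines may also contribute, as the design implies, but it was not tested, and the doubt about both labels bears on it.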

How the results depend on the processing

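Thinning, the fits without both libraries numbered 3, over genes tested in both lines and without the MHC region were chosen after the data were seen. A 2-fold minimum left 1161 genes in C4-2, 2055 in DU145, 2452 for the interaction and 96 shared in direction, since it removes smaller changes by construction. DESeq2 gave 4155, 8058 and 5296 genes. Genes called in both lines in the same direction numbered 1267 with it, and the cause was not tested. With an estimated correlation 8, 4 and 9 lists passed in C4-2, DU145 and the interaction. That option also gives camera's t test only the residual degrees of freedom, and lists with correlations below 0.01 lost calls too (respiratory chain in C4-2, 0.003), so correlation alone is not the cause. All other alternatives kept these counts within 1.5 times of 6184, 8924, 6064 and 1930 genes and 13, 15 and 16 lists. Leaving out 1 library gave 5035 to 5751 genes in C4-2, 8112 to 9054 in DU145, 4743 to 6249 for the interaction and 1619 to 2020 shared, and 12 to 15, 13 to 15 and 13 to 16 lists. A lone DMSO library was then assumed to vary like the treated ones.

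With the replicate block, 5699, 9953 and 6037 genes passed, 2049 were shared, and 13, 15 and 17 lists passed. The block added calls for TBK1, RB1 and CDKN2A in DU145 and for epithelial-mesenchymal transition genes in the interaction (adjusted p = 0.0301, against 0.0714), and changed no other call of a named gene or list. In the libraries labelled C4-2, 2 pairs share only a number, with correlations of -0.02 and 0.02. Depth limited the calls: DU145 thinned to the C4-2 depth gave 6189 genes. Without both libraries numbered 3 it gave 9343. Over genes tested in both lines the interaction gave 5910, and without the MHC region C4-2 gave 6172. Named genes were compared only with DESeq2, library totals, the replicate block and each library left out. Of 236 log2 fold changes of named genes, 12 changed their call under some of these settings and 0 reversed. The call was also lost for COL1A1, SRRM4 and SCG5 in DU145 and for H2BC12 in C4-2 under some of these settings. Whether named genes keep their calls under the other alternatives was not tested.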

Other observations

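The tests of the luminal genes in this part were chosen after the results were seen, while those of the MHC region and of other splits of the libraries were chosen before. Glycolysis and hypoxia genes did not pass camera in either line (adjusted p = 0.95 in C4-2 and 0.782 in DU145), but their members moved apart. In the libraries labelled C4-2, 10 of 24 rose, including NDRG1 (1.94), SLC2A3 (1.33) and VEGFA (0.85), and 10 fell, including TPI1 (-0.69) and ENO1 (-0.46). The list's median was -0.06 and its mean 0.10. In DU145, ADM (1.55) and PFKFB4 (1.17) were among 4 of 27 that rose, and 12 fell. The cholesterol list, which rose in DU145, did not pass in C4-2 (adjusted p = 0.501), where MSMO1 (0.99) rose, and neither did the fatty acid list (adjusted p = 0.909).

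Several lists passed in neither line or in one. In C4-2, camera adjusted p was 0.909 for p53, 0.433 for luminal prostate, 0.218 for immediate early, 0.507 for epithelial-mesenchymal transition and 0.798 for neuroendocrine genes, whose median was -0.14 although camera pointed higher. The luminal prostate list passed there once genes in more than 1 list were removed (adjusted p = 0.0367). THBS1 (-1.77), KRT8 (-1.34) and KRT18 (-1.42) fell. Only 4 histone genes and 4 leukocyte and stromal markers could be tested in C4-2, too few for camera. H2AC6 (2.6), H2BC5 (1.65) and H2BC12 (0.76) rose, the last not with DESeq2 (adjusted p = 0.0918), and ACTA2 (-2.05) and COL1A1 (-0.50) fell. CSF1R also fell (-1.76), but not without DMSO replicate 2 (-1.61, adjusted p = 0.0746). In DU145, camera adjusted p was 0.479 for histone, 0.213 for MHC class I, 0.505 for heterochromatin, 0.213 for epithelial-mesenchymal transition, 0.881 for neuroendocrine, 0.708 for respiratory chain, 0.229 for NRF2 and 0.505 for leukocyte and stromal genes, of which CD14 rose (3.49, from 0.329 to 3.70 CPM). HLA-E (1.12) rose and COL5A1 (-1.05) fell. In the interaction, adjusted p was 0.203 for histone, 0.859 for pathway, 0.222 for MHC class I, 0.821 for luminal prostate, 0.859 for neuroendocrine, 0.325 for ribosomal protein, 0.775 for glycolysis and 0.228 for leukocyte and stromal genes. For mitochondrial genes it was 0.859, which says nothing about the lines, since none of these genes had a count in the C4-2 table. The pathway list's median interaction was 0.06 and its mean -0.29 with camera pointing lower, the glycolysis list's mean was -0.10 although its median was above 0, and the luminal prostate list's median was 0.24 although its mean was below 0. For epithelial-mesenchymal transition genes it was 0.0714, which passed without DU145 palbociclib replicate 3 (adjusted p = 0.0361), with library totals (0.0462), without genes in more than 1 list (0.0359), with DU145 thinned (0.0383) and with the replicate block (0.0301), but not with an estimated correlation (0.22).

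Over genes tested in both lines, a set chosen after their values were seen, the largest interactions included KIFC1 (6.50), FAM111B (3.90) and HAS3 (3.54) with the higher change in DU145, and MPP7 (-5.24), CHAC1 (-4.58), CTH (-4.43) and INHBE (-4.26) with the lower. MPP7 changed by 3.74 in C4-2 and -1.40 in DU145.

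The libraries labelled C4-2 held 0 counts of KLK3, KLK2, ACP3 and FOLH1, and 3 explanations were examined. Over the summed counts of the 5 libraries, 0 counts allow at most 0.195 CPM, which argues against shallow depth. Loss in alignment or counting was left open. Of 61 listed G2/M genes, 57 were tested in these libraries and all 61 in those labelled DU145. NUSAP1 and SKA1 had 0 or 1 counts per C4-2 library, SPC25 0 to 4 and PRC1 2 to 7, although MKI67 was at 813 CPM with DMSO. Some genes of dividing cells were thus nearly absent from this table, which does not decide the luminal genes. Over the 27 luminal prostate list members counted in both tables, the median log2 ratio of C4-2 to DU145 was 0.20 (95% bootstrap interval -1 to 0.45). These members went both ways over a wide range. That median also left out 4 members counted in C4-2 and at 0 in DU145 (TMPRSS2, STEAP1, TRPM8 and TMEFF2). Of 24 basal and mesenchymal genes, 20 were higher in the libraries labelled C4-2 than in those labelled DU145, although the list was made of genes typical of DU145, which is consistent with a mislabelled sample or other cells. Levels were set across tables counted differently, both treatments share the pattern, and no biological explanation was tested.

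Genes of the MHC region were low in the C4-2 table. Of 89 genes in chromosome 6 from 28 to 34 Mb with at least 10 CPM in DU145, 50 lay under 1 CPM there, or 56.2%, against 4.6% of 9653 genes elsewhere (Fisher's exact test across genes, p = 6.91e-42). RPS18, a ribosomal protein gene of the region that all cells need, was at 1.5 CPM in the C4-2 table and 936 CPM in DU145, a log2 ratio of -9.28 where 59 other ribosomal protein genes ranged from -7.23 to 0.32, which argues against lower transcription in these cells. A candidate explanation is that reads shared with alternative copies of the region in the reference were not counted, although a reference with such copies is not named in the sources used here. ITPR3, near the edge of the region, was at 329 CPM in C4-2 and 366 in DU145. The falls of KIFC1 and the low levels of TAP1 and HLA-E in that table are open to this loss. So is the interaction of RING1, which lies in the region at 0.715 CPM in the C4-2 table and 83.0 CPM in DU145.

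The 6 DU145 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 8924 genes and 15 lists, and 1 of the 10 splits gave as many of each. The highest of the other splits gave 0 genes and 10 lists. Each of the other splits mixed palbociclib and DMSO libraries within both groups, which widened the spread and left little room for gene calls. Their groups also held the treatments in unequal numbers. These splits therefore do not show what would pass without a treatment effect. Among the 4 splits that part all 3 pairs, the other 3 gave 0 genes and 8 to 10 lists.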
